A study of Mus musculus with 6 samples.

How the data were processed

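The series holds 6 Illumina MouseRef-8 v2.0 bead arrays, 1 per embryo, of frontal cortex from male C57BL/6J embryos at embryonic day 15, 3 carrying a Cyfip1-spanning bacterial artificial chromosome and 3 wild-type littermates. Per the labels' protocols, total RNA was extracted with an RNeasy kit, checked on a Nanodrop and a Bioanalyzer, and 200 ng was amplified, biotin-labelled and hybridised. The labels treat the samples as separate animals, each with its own animal number. Samples were grouped by the genotype in the labels and numbered within a group only to name them, so no number pairs a transgenic with a wild-type sample. All 6 arrays carry the same slide number in the labels, so slide was no covariate.

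The deposited scanner table gives 1 linear intensity per probe and array, with replicate beads already summarised. BeadStudio is named in the submitters' processing notes, while its version and settings are not given in the sources used here. No intensity lies below 72.8, so the deposited intensity values appear not to be background-subtracted, and the column medians differ between arrays. The deposited value table is on a log2 scale, and comparison with the scanner table showed that the authors' log2 values equal quantile normalization of the log2 intensities without background correction, to within 5e-09. Their median is 7.18 in every array, they are not centred, and each column increases with its array's intensity.

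The main values were computed from the scanner table. A correction that uses detection p-values had been chosen before the data were examined, with a fallback for the case that none were at hand. The tables used here hold no detection p, so the fallback was used. Intensities were background-corrected with limma's normexp and an offset of 50, put on a log2 scale and quantile-normalized, and probes whose mean log2 intensity over the 6 arrays lay above the median of all probes were tested, 12848 of 25697. The versions were R 4.3.3 and limma 3.58.1. Each probe was tested with lmFit and eBayes, two-sided, transgenic minus wild-type with no covariate, and p-values were adjusted by Benjamini-Hochberg over all tested probes with a threshold of 0.05. An exact permutation test of 3 against 3 samples cannot give a p below 0.1, so none was used to call a gene. The test was tried on simulated arrays with known changes before it was applied. Where the spread of a typical probe was simulated, it recovered 22.4% of changes of 0.5 on the log2 scale and 100% of changes of 1, and called 0.150% of 12639 unchanged probes. With the spread of these samples it recovered 1.72% and 21.1% of the same changes and called 0.00791% of the unchanged probes. Both spreads were taken from the log2 scanner intensities before normalization and so include brightness differences between arrays. The shares may therefore understate recovery in the normalized values that were tested. A simulated list shifted by 0.5 was called by camera with the preset correlation, with an adjusted p of 3.6e-09, and missed the threshold with an estimated correlation, with an adjusted p of 0.0658, where the spread of these samples was used. Genes were simulated independently of each other, so how often camera calls an unshifted list of correlated genes was not examined.

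Probes were named through the platform's annotation table and gene identifiers were looked up in the RefSeq genes of the mouse assembly GRCm38.p6, which served only for names and gene order. 23978 probes had 1 gene, 0 had several and 1719 had no name here. 23962 of the named probes were found by gene identifier, 16 were not and kept the annotation's symbol, and 0 symbols changed. The tested probes included 12119 named ones for 9080 genes and 729 without a name, 19 of which were higher at an unadjusted p under 0.05. No probe bore the name Cyfip1. No coordinates are given because no genome build accompanies the arrays.

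31 gene lists were fixed before the data were examined, from the tissue, the transgene, the title of the study and other cell types the dissection could hold. They cover the WAVE and Arp2/3 complexes, FMRP and translation initiation, mTOR signalling, ribosomal proteins, sterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, the cell classes of cortex, ganglionic eminence, non-cortical brain, vessels, blood, meninges, choroid plexus, muscle and skin, synapse, axon guidance, autism-associated genes, stress genes, the interferon response, the neighbours of Cyfip1 and sex-specific genes. Each gene was represented by its tested probe of highest mean intensity. 29 lists were tested with limma's camera at its preset correlation of 0.01 and adjusted by Benjamini-Hochberg over the lists, while neighbours of Cyfip1 and sex-specific genes were described only. For each list the members were also adjusted over the list alone.

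Genes were named by a rule set beforehand. It takes Cyfip1 and its neighbours, up to 12 probes in each direction with the largest change among those past the threshold, and, where fewer pass, fills the places with named probes of smallest unadjusted p whose groups do not overlap, 1 per gene. Since no probe passed, all 24 places were filled in that way. From each list described, up to 4 members of smallest unadjusted p are named. The sex-specific genes and the genes that bear on the tissue in single samples (Myl1, Krt14, En2, Irx2 and Ttr, and in the closing part Otx2, Actc1, Dlx1 and Tbr1) fall outside the rule. Those that bear on the tissue were chosen after their values were seen.

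The alternatives were no background correction, which gives the authors' values, cyclic loess, scaling to a common median, no intensity filter, an intensity trend with a robust prior, array weights, the animal number range as a block, each sample left out in turn, an estimated correlation in camera, fry, the mean of all probes of a gene, and other thresholds. Added after the data were seen were leaving out transgenic sample 1 and wild-type sample 2 together, the 4 animals numbered over 200 alone, the brightest 25% of probes, the mean of muscle and skin genes as a covariate, and the number range as a block together with an estimated correlation.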

Results

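Gene expression was measured in frontal cortex of male C57BL/6J mouse embryos at embryonic day 15. Cortical neurons are being born at this stage. 3 embryos carried a bacterial artificial chromosome that spans Cyfip1 and 3 were wild-type littermates. Cyfip1 encodes a partner of the fragile X protein FMRP, of the cap-binding factor eIF4E and of the WAVE complex, which drives branched actin assembly. RNA of each embryo was hybridised to its own Illumina MouseRef-8 array, a bead array read in 1 colour, and the number of arrays limits the precision of every value. Median scanner intensity ranged from 130.3 in wild-type sample 3 to 178 in transgenic sample 3. The mean correlation across probes with the other arrays was 0.929 for transgenic sample 1 and between 0.954 and 0.969 for the others. Genes of skeletal muscle and skin were bright in transgenic sample 1. Myl1, a muscle myosin light chain, stood at a log2 intensity of 12.90 there and at 11.05 in wild-type sample 3, against 6.69 to 6.74 in the other 4 samples. Krt14, a keratin of the epidermis, stood at 11.29 and 9.05 in the same samples and at 6.18 to 6.43 in the others. In wild-type sample 2, En2 and Irx2, transcription factors of midbrain and hindbrain, stood at 12.22 and 11.94, while En2 ranged from 6.50 to 10.96 and Irx2 from 7.01 to 9.38 elsewhere. The animal numbers in the labels fall into 2 ranges, under 100 for transgenic sample 1 and wild-type sample 3 and over 200 for the other 4 samples, and the labels do not say what the numbers mean.

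The only contrast in the design is transgenic against wild-type, and it asks how extra Cyfip1 alters the transcriptome of the developing cortex, with mTOR signalling as the pathway the study's title names. No array probe carried the name Cyfip1 in the annotation used, so the level of the transgene was not analysed here and the group labels were not checked against it. Genes next to Cyfip1 on the chromosome were close to wild-type level. Nipa2 and Nipa1, magnesium transporters that follow Cyfip1 in gene order, differed by 0.08 (SE 0.18) and -0.19 (SE 0.29) on the log2 scale, and neither sign held in every setting tried. Herc2, a ubiquitin ligase gene after them, was at 11.61 ± 0.20 in transgenic and 11.99 ± 0.04 in wild-type samples (log2 intensity, SD, n = 3 each), a difference of -0.39 with non-overlapping groups that did not pass (limma adjusted p = 0.668). Ube3a differed by -0.05 (SE 0.13) and Atp10a by 0.25 (SE 0.25), and the sign of Ube3a turned under cyclic loess and median scaling. 0 of the 5 flanking genes tested passed over all probes and 0 passed adjusted over the list alone. Probes of Tubgcp5, Gabra5, Gabrg3 and Oca2 were too dim to be tested. The Y-linked genes Eif2s3y, Kdm5d and Uty were expressed in all 6 samples, with differences of -0.06, 0.05 and -0.11 and 0 of the 3 past the threshold over all probes or adjusted over the list alone. Both Xist probes lay below the intensity filter, and the labels call every embryo male.

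The gene with the smallest p in either direction was Ifitm3, and 3 of the 12 genes named for higher expression, B2m, Ifi27 and Bst2, belong to the interferon response list fixed beforehand. Ifitm3, an interferon-induced membrane protein that restricts viral entry, stood 3.59-fold higher in transgenic samples, at 10.48 ± 0.02 against 8.63 ± 0.32 (log2 intensity, SD, n = 3 each). B2m, the light chain of MHC class I, differed by 1.34 (SE 0.20), the interferon-inducible gene Ifi27 by 1.69 (SE 0.32), Samd9l by 1.20 (SE 0.23) and Bst2, which tethers budding viruses to the cell surface, by 1.07 (SE 0.20). None of them passed the adjusted threshold, and Ifitm3 came closest (limma adjusted p = 0.276). For the next probe and for every other gene of this group the adjusted p was 0.668. Lyz1, a lysozyme, was higher by 1.63 (SE 0.29), Lgals9, a galectin, by 0.82 (SE 0.14) and Tspo, a mitochondrial membrane protein, by 0.91 (SE 0.17), again without passing. The remaining genes that filled the 12 places were the homeobox gene Msx1 (1.35), the forkhead gene Foxa1 (1.78), the matrix proteoglycan Prelp (1.01) and the RNA-binding protein Rbm47 (1.26). The rule that named these 12 genes required all 3 transgenic values to lie above all 3 wild-type values. A second probe of B2m and of Ifi27, and both further probes of Tspo, had the same sign.

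The 12 genes named for lower expression include Nlgn3 of the synapse list, Ank2, Scn1a and Nlgn3 of the autism list and Mtor of the mTOR list, and none of the 12 passed. Negr1, a neuronal adhesion molecule, stood at 8.03 ± 0.39 in transgenic and 9.29 ± 0.27 in wild-type samples (log2 intensity, SD, n = 3 each), a difference of -1.25 (SE 0.24). Adgrl3, the adhesion receptor latrophilin 3, differed by -0.94 (SE 0.19), Ank2, a membrane scaffold, by -0.85 (SE 0.17), the sodium channel Scn1a by -0.65 (SE 0.13) and the postsynaptic adhesion molecule Nlgn3 by -0.60 (SE 0.13). Trim46, which organises microtubules at the start of the axon, differed by -0.77 and Mycbp2, a ubiquitin ligase of growing axons, by -0.83. Crtc1, a coactivator of CREB, differed by -0.64, Pbx3 by -0.90, Tro by -0.60 and Atp9a by -0.59. Mtor, the kinase at the centre of mTOR signalling, was the twelfth, at 9.18 ± 0.14 in transgenic and 9.70 ± 0.05 in wild-type samples, a difference of -0.53 (SE 0.12), and another Mtor probe was too dim to be tested. The limma adjusted p of every gene in this group was 0.668.

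**Figure D1:**
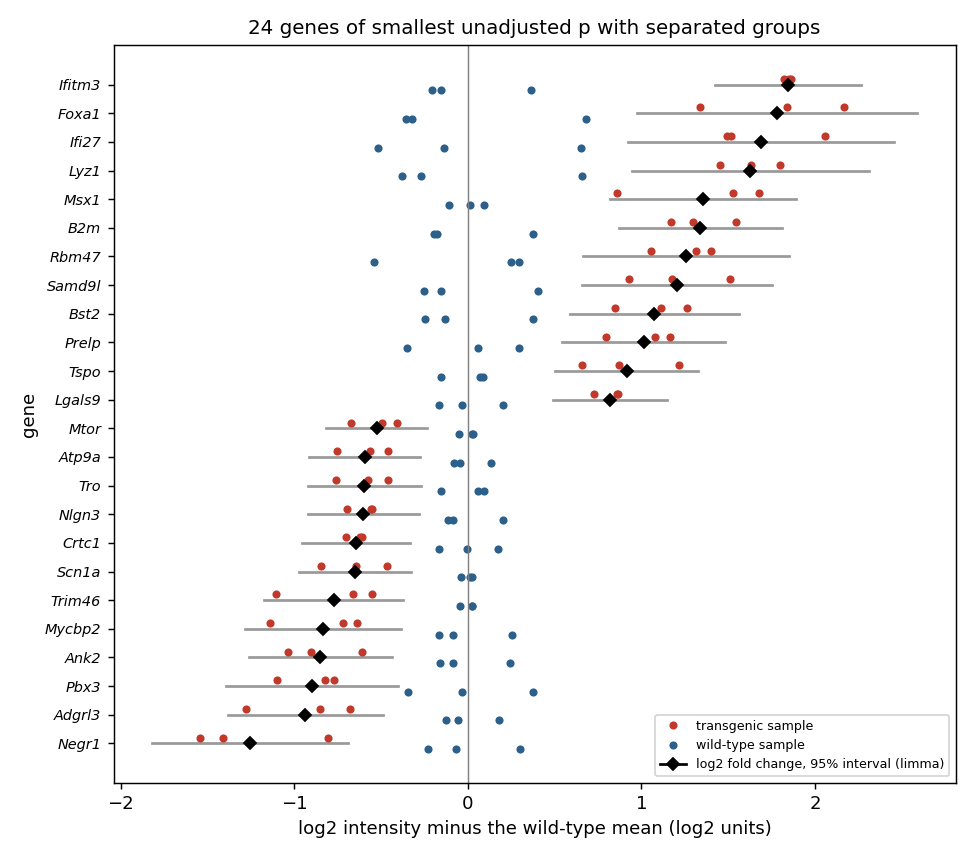
Log2 intensity of the 24 named genes of smallest unadjusted p, 12 higher and 12 lower in transgenic samples, drawn relative to the wild-type mean of each gene; red points are transgenic and blue points wild-type samples, and black diamonds with grey bars give the limma log2 fold change and its 95% interval. The transgenic values of Ifitm3, 10.45 to 10.50 in log2 intensity, spread least, and no gene in the plot passed the adjusted threshold.

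Across the 12848 probes tested, 0 were higher and 0 lower at a limma adjusted p under 0.05, while 464 were higher and 452 lower at an unadjusted p under 0.05, 916 together where 642.4 would pass by chance. That total was 418 without wild-type sample 2, 552 without transgenic sample 1 and 360 without both, each below the chance count, and 1978 with the animal number range as a block. With another sample left out it stayed above the chance count. It was 1147 without transgenic sample 2, 856 without transgenic sample 3, 956 without wild-type sample 1 and 730 without wild-type sample 3. At an unadjusted p under 0.005 there were 40 higher and 20 lower probes, 60 against 64.24 by chance. Groups did not overlap for 1823 probes, 14.2% where chance gives 10%. Other divisions of the 6 samples into 3 against 3 gave between 3.63% and 17.08%. Grouping wild-type sample 3 with transgenic samples 1 and 2 gave 15.99%, and with transgenic samples 1 and 3 it gave 17.08%. The remaining divisions gave smaller shares than genotype. A share above 10% was therefore not particular to genotype. Scaling each array to a common median in place of quantile normalization changed the split at an unadjusted p under 0.05 to 850 higher and 89 lower, and moved the median of all probes by 0.07. In simulated arrays with the spread of these samples, the same limma test on 12848 probes recovered 1.72% of probes changed by 0.5 on the log2 scale, 21.1% of those changed by 1 and 83.6% of those changed by 2. That spread was measured before normalization and includes brightness differences between arrays, so these shares may understate recovery in the tested values.

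By camera with its preset correlation, 11 of 29 lists passed, 9 towards higher and 2 towards lower values in transgenic samples. With the correlation estimated from the data 0 passed, the smallest adjusted p being 0.442, and fry, which asks whether a set moves one way on balance, called 0 with a smallest adjusted p of 0.131. When the 6 samples were divided in the 9 other ways into 3 against 3, camera with the preset correlation called between 7 and 13 lists, a range that includes the 11 of genotype. In the account of the lists that follows, no member passed over all probes.

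Genes of immune cells and of the coverings and vessels of the brain were higher on average in transgenic samples. Sample means of the meningeal, endothelial and choroid plexus lists overlapped between the groups. All 15 tested microglia and macrophage genes lay above 0 (median log2 fold change 0.77, camera adjusted p = 6.66e-11, adjusted p = 0.442 with an estimated correlation), and 5 passed adjusted over the list alone. Of this list 21 genes had a probe, and those not tested were too dim. The microglia and macrophage median was 0.52 with no intensity filter, 0.58 without wild-type sample 3 and 1.08 without wild-type sample 1. Lyz2 differed by 1.27, the complement gene C1qb by 1.02, and the Fc receptor genes Fcer1g and Fcgr3 by 1.12 and 0.74. Wild-type sample 1 lay close to the transgenic samples for this list, with a list mean of 0.21 relative to the 6-array mean, against 0.27 to 0.51 in transgenic samples and -0.59 and -0.75 in the other wild-type samples. Of the 26 interferon response genes with a probe only 10 were tested, the others being too dim. Of these 10, 9 lay above 0 (median 0.70, camera adjusted p = 1.76e-06, adjusted p = 0.442 with an estimated correlation), and 3 passed adjusted over the list alone. Beside B2m, Ifi27 and Bst2, the ubiquitin-like modifier Isg15 differed by 0.70. The interferon median was 0.41 without transgenic sample 2 and 0.20 with no intensity filter, and the difference of the list means was 0.64 within the pair of animals numbered under 100 and 0.72 among the 4 numbered over 200. All 27 meningeal and fibroblast genes lay above 0 (median 1.17, camera adjusted p = 3.11e-13, adjusted p = 0.442 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Igfbp2 differed by 0.64, the collagen gene Col3a1 by 2.22, the matrix gene Lum by 2.37 and Foxd1 by 1.11. The same transgenic sample 1 that was bright for muscle and skin genes had the highest meningeal mean, 1.70 against 0.04 and 0.21 in the other transgenic samples. Wild-type sample 1, at 0.06, lay above transgenic sample 2, at 0.04. The median was 0.74 without transgenic sample 1, 0.44 without it and wild-type sample 2, and 0.60 among the 4 animals numbered over 200. Endothelial genes had a median of 0.44 (camera adjusted p = 2.14e-06, adjusted p = 0.467 with an estimated correlation), 15 of 18 above 0, 0 adjusted over the list alone, with Emcn at 1.26, Egfl7 at 0.72, Eng at 0.64 and Robo4 at 0.67. A second Robo4 probe had the opposite sign. The endothelial mean of wild-type sample 1, 0.03, lay above that of transgenic sample 2, 0.01. Choroid plexus genes had a median of 1.29 (camera adjusted p = 8.15e-06, adjusted p = 0.442 with an estimated correlation), 9 of 11 above 0 and 3 adjusted over the list alone, with Aqp1 at 2.41, Clic6 at 2.40, Ecrg4 at 2.0 and Msx1 at 1.35. Transgenic sample 3 had the highest choroid plexus mean, 1.60, and the median was 0.80 without it and 0.54 with no intensity filter. The difference of the choroid plexus means was -0.05 within the pair of animals numbered under 100 and 2.01 among the other 4. The mean difference thus did not hold within the first range, but members went both ways there. Aqp1 stood at 10.71 in transgenic sample 1 and 7.60 in wild-type sample 3, and Ttr at 9.00 and 13.48. Both differences of means depend strongly on Ttr.

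Synaptic genes were lower in transgenic cortex on average, with sample means that overlapped between the groups. Of 39 tested, 37 lay below 0 (median -0.39, camera adjusted p = 8.15e-06, adjusted p = 0.610 with an estimated correlation), and 0 passed adjusted over the list alone. Besides Nlgn3, the postsynaptic scaffold Dlg4 differed by -0.51, the vesicle protein Syt4 by -0.57 and the presynaptic adhesion molecule Nrxn2 by -0.72. Transgenic sample 1 had the lowest synaptic mean, -0.57, while transgenic sample 2, at 0.11, lay above wild-type sample 3, at 0.05. The median was -0.14 without transgenic sample 1, -0.22 without wild-type sample 1, -0.15 without transgenic sample 1 and wild-type sample 2, and -0.23 among the 4 animals numbered over 200. Array weights gave -0.24, the mean of muscle and skin genes as a covariate -0.20 and no intensity filter -0.20. Autism-associated genes were also lower, 20 of 25 below 0 (median -0.16, camera adjusted p = 5.94e-04, adjusted p = 0.442 with an estimated correlation). 3 of them passed adjusted over the list alone. The members of smallest p were Ank2, Scn1a, Nlgn3, which the synaptic list also holds, and Pcdh10, a protocadherin that differed by -0.52. The autism median was -0.10 under median scaling and -0.27 without transgenic sample 1 and wild-type sample 2.

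**Figure D2:**
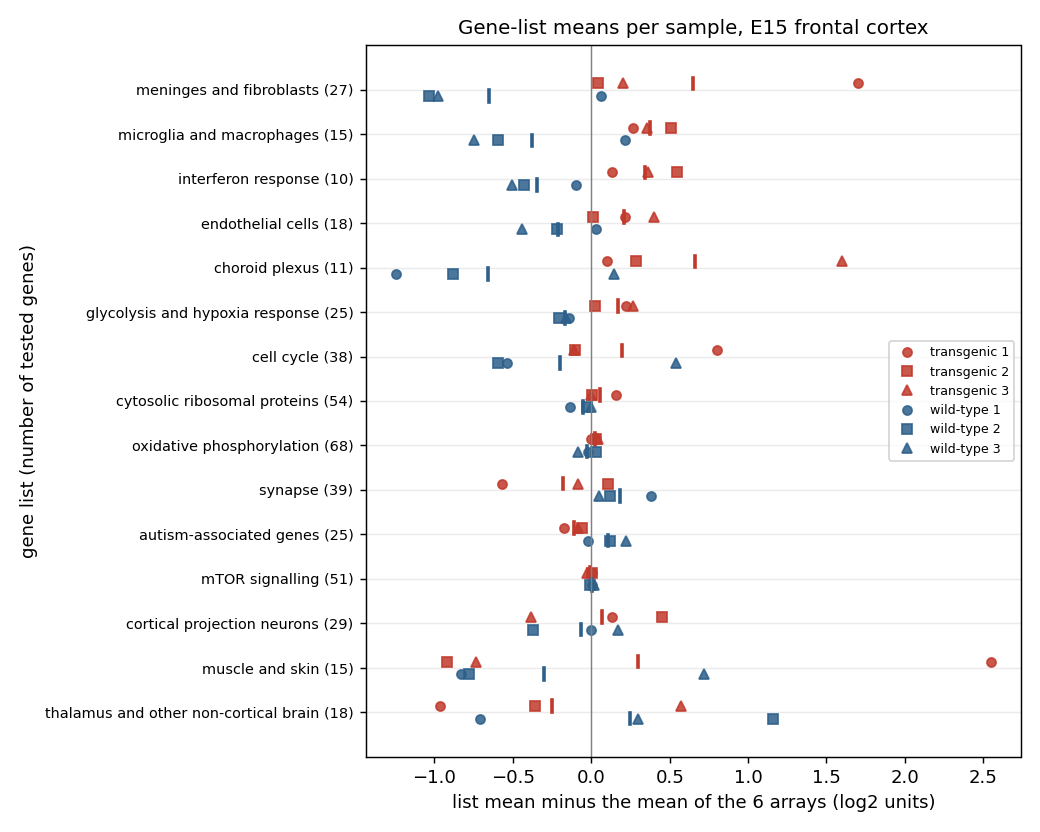
Mean log2 intensity of each gene list in each of the 6 samples relative to the mean of all arrays, with the number of tested genes in brackets; red symbols are transgenic and blue symbols wild-type samples, the symbol shape gives the sample number and short vertical lines are group means. Transgenic sample 1 reaches 1.70 for meningeal genes and 2.55 for muscle and skin genes, wild-type sample 2 reaches 1.16 for genes of non-cortical brain, and the mTOR means of all samples lie between -0.03 and 0.02.

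The 51 tested genes of mTOR signalling showed no common direction. 20 lay above 0 and 31 below, with a median of -0.04 (camera adjusted p = 0.781, adjusted p = 0.801 with an estimated correlation) that turned positive under cyclic loess and median scaling, and 0 passed adjusted over the list alone. Besides Mtor, the growth factor Igf2 differed by 0.90, the PI3-kinase subunit Pik3cd by -0.54 and the lysosomal anchor Lamtor1 by 0.32. Igf2 is also in the meningeal list. Genes of FMRP and cap-dependent translation had a median of 0.01 (camera adjusted p = 0.221), 0 of 14 adjusted over the list alone. In that list Eif4ebp1, the repressor of eIF4E, differed by 1.0, Mknk1 by 0.31, Eif4e2 by 0.32 and Pabpc1 by 0.15, and further probes of Eif4e2 and Pabpc1 did not all share the sign. Genes of the WAVE and Arp2/3 complexes had a median of 0.04 (camera adjusted p = 0.336), 0 of 17 adjusted over the list alone. Abi3 differed by 0.54, Arpc1b by 0.84, Nckap1l by 0.41 and Abi2 by -0.32, and Abi3 and Nckap1l are subunits known from blood-derived cells.

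Ribosomal, glycolytic and mitochondrial genes lay slightly higher in transgenic samples. Of 25 genes of glycolysis and the hypoxia response, 20 lay above 0 (median 0.34, camera adjusted p = 1.32e-05, adjusted p = 0.442 with an estimated correlation), 0 adjusted over the list alone. Ldha, which makes lactate, differed by 0.68, Pdk1, a kinase that inhibits pyruvate dehydrogenase, by 0.57, the oxygen sensor Egln3 by 0.57 and the stress gene Ndrg1 by 1.42. The 3 transgenic list means, 0.02 to 0.27, lay above the 3 wild-type ones, -0.21 to -0.14, and the median was 0.22 without transgenic sample 1. Cytosolic ribosomal protein genes had a median of 0.13 (camera adjusted p = 6.89e-05, adjusted p = 0.610 with an estimated correlation), 45 of 54 above 0 and 0 adjusted over the list alone. Rpl4 differed by 0.34, Rpl7a by 0.41, Rps3a1 by 0.34 and Rps20 by -0.26. The ribosomal call was lost under median scaling (camera adjusted p = 0.0649), and the median was 0.06 without transgenic sample 1 and 0.08 without it and wild-type sample 2. Oxidative phosphorylation genes had a median of 0.06 (camera adjusted p = 0.0146, adjusted p = 0.610 with an estimated correlation), 50 of 68 above 0 and 0 adjusted over the list alone, with Uqcrh at 0.24, Ndufb9 at 0.19, Ndufab1 at 0.19 and Ndufa4 at -0.31. That call was lost without wild-type sample 3 (median 0.03, camera adjusted p = 0.433), transgenic sample 2 (adjusted p = 0.0704) or transgenic sample 3 (adjusted p = 0.0826), under median scaling (median 0.10, adjusted p = 0.30) and among the 4 animals numbered over 200 (median 0.04, adjusted p = 0.229), and the median was 0.11 without transgenic sample 1 and wild-type sample 2.

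Cell cycle genes were higher in transgenic samples as a group, and none by itself. All 38 tested lay above 0 (median 0.38, camera adjusted p = 1.47e-05, adjusted p = 0.610 with an estimated correlation), 0 of them at an unadjusted p under 0.05 and 0 adjusted over the list alone. The replication helicase gene Mcm6 differed by 0.55, Ccnd2 by 0.58, Cdk2 by 0.62 and Hmgb2 by 0.58. Transgenic sample 1 and wild-type sample 3, the samples with bright muscle genes and with animal numbers under 100 in the labels, had the highest cell cycle means, 0.80 and 0.54. The other samples, numbered over 200, stood at -0.10 and -0.11 in transgenic and -0.54 and -0.59 in wild-type cortex. The difference of the list means was 0.26 within the first pair and 0.46 among the other 4 samples. The list lost its call without transgenic sample 1 (median 0.09, camera adjusted p = 0.233), and the median was 0.23 without wild-type sample 1, 0.18 without wild-type sample 2, 0.81 without wild-type sample 3, 0.18 with the mean of muscle and skin genes as a covariate, and -0.10 without transgenic sample 1 and wild-type sample 2.

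The lists for the classes of cells that build the cortex did not pass camera with the main values. Wild-type sample 2 had an interneuron mean of -0.61, against 0.35 and 0.50 in the other wild-type samples. Its ganglionic eminence and striatum mean was -0.57, against 0.23 in each of the others. Its projection neuron mean, -0.37, lay near the -0.38 of transgenic sample 3. The differences of these lists thus depend in part on single samples. Radial glia had a median of -0.11 (adjusted p = 0.558), intermediate progenitors -0.07 (adjusted p = 0.919), cortical projection neurons 0.01 (adjusted p = 0.919), interneurons -0.34 (adjusted p = 0.154), ganglionic eminence and striatum 0.05 (adjusted p = 0.919) and Cajal-Retzius cells with the cortical hem -0.01 (adjusted p = 0.438). Astrocyte genes had a median of 0.42 (adjusted p = 0.443), oligodendrocyte lineage genes -0.11 (adjusted p = 0.743), pericyte and smooth muscle genes 0.05 (adjusted p = 0.224), erythroid genes -0.08 (adjusted p = 0.373), axon guidance genes -0.12 (adjusted p = 0.373), sterol and fatty acid synthesis genes -0.13 (adjusted p = 0.154) and immediate early and stress genes 0.07 (adjusted p = 0.0969). Genes of thalamus and other non-cortical brain had a median of -0.49 (adjusted p = 0.0957), with Zic4 at -1.54, Zic1 at -0.80, Lhx9 at -1.64 and Zic2 at -0.62, and muscle and skin genes one of 0.61 (adjusted p = 0.0969), with Krt8 at 1.44, Krt18 at 1.10, Des at 0.64 and Myog at -0.20. 0 members of these 15 lists passed adjusted over the list alone. Mean and median differed in sign for Cajal-Retzius cells, oligodendrocytes and intermediate progenitors, and for ganglionic eminence and striatum camera's direction was down while the median was above 0. Interneurons passed without wild-type sample 2 (median -0.47, camera adjusted p = 6.4e-04), without it and transgenic sample 1 (median -0.33, adjusted p = 0.00323) and under median scaling (median -0.32, adjusted p = 0.0319), and Cajal-Retzius cells passed towards higher values without transgenic sample 1 (median 0.39, adjusted p = 0.0258) and without it and wild-type sample 2 (median 0.58, adjusted p = 1.67e-05). Non-cortical brain passed under cyclic loess (adjusted p = 0.0337), under median scaling (adjusted p = 0.00309) and without transgenic sample 3 (median -0.73, adjusted p = 0.00309) or wild-type sample 1 (median -0.84, adjusted p = 0.00164). Muscle and skin genes passed with the animal number range as a block (adjusted p = 0.00268), with no intensity filter (adjusted p = 0.0352) and without transgenic sample 2 (median 1.29), transgenic sample 3 (median 1.18) or wild-type sample 3 (median 1.24), and towards lower values without transgenic sample 1 (median -0.56, adjusted p = 0.0476) or without it and wild-type sample 2 (median -0.73, adjusted p = 3.7e-04). Erythroid genes passed without transgenic sample 1 (median -0.17, adjusted p = 0.00644), without it and wild-type sample 2 (median -0.16, adjusted p = 0.00643) and among animals numbered over 200 (median -0.18, adjusted p = 0.0361), and pericytes without wild-type sample 1 (median 0.15, adjusted p = 0.0478).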

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

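The alternatives without transgenic sample 1 and wild-type sample 2, with only animals numbered over 200, with the brightest 25% of probes, with the mean of muscle and skin genes as a covariate and with the number range block and estimated correlation were chosen after the data were seen. 0 probes passed an adjusted p of 0.05 by limma in any setting and 0 passed 0.1 with the main values, the smallest adjusted p ranging from 0.0765 among animals numbered over 200 to 0.993 without transgenic sample 1 and wild-type sample 2, with 0.0909 without wild-type sample 1 as the only other one under 0.1, and 40 higher and 20 lower probes had an unadjusted p under 0.005. Camera called between 9 and 14 lists in the settings with the preset correlation, and 0 with an estimated correlation, 0 with fry and 0 with the number range block and estimated correlation. Of 1479 values of 84 named genes under the alternatives, 1468 kept their sign and side of the threshold and 11 changed sign. Much of this was fixed in advance. No probe passed in any setting, and genes named for groups that do not overlap cannot change sign when a sample is left out. The number range block and the robust prior also leave every log2 fold change as it was. Of 632 values of 29 lists, 528 kept sign and side, 40 lost their call, 16 gained one and 48 changed sign, 4 of these past the threshold. Except where stated, the cause was not tested. The planned filter on detection p-values was not run, since the tables used here hold none, and the planned normexp setting with an offset of 50 became the main one. No paired analysis was possible because sample numbers were given in the order of the labels and pair no samples, so the animal number range was used as a block instead. Dim probes have values near the offset and background, so folds of genes at a log2 intensity near 6 or 7 are compressed.

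Under cyclic loess, Ube3a stood at 0.0027, mTOR signalling at 0.0018 and Cajal-Retzius cells at 0.0402, and under median scaling the same 3 stood at 0.0622, 0.0534 and 0.0946, a setting that moves the median of all probes by 0.07, though not every probe alike. With no filter the Cajal-Retzius median was 0.0013. Array weights gave 0.0057 for Nipa1 and medians of -0.011 for FMRP and translation, -0.0737 for projection neurons, 0.14 for interneurons, 0.0916 for Cajal-Retzius cells and -0.0301 for muscle and skin. The mean of all probes of a gene gave -0.00387 for WAVE and Arp2/3, 0.0232 for intermediate progenitors and 0.0817 for Cajal-Retzius cells. The brightest 25% of probes gave -0.0311 for WAVE and Arp2/3, 0.0105 for mTOR signalling and 0.0377 for intermediate progenitors. Without transgenic sample 1 and wild-type sample 2, Nipa2 was at -0.10, Atp10a at -0.11, Nipa1 at 0.10, Ube3a at 0.0368 and Des at -0.0283, and the medians were -0.10 for cell cycle, -0.10 for projection neurons, -0.15 for ganglionic eminence and striatum, 0.58 for Cajal-Retzius cells, 0.14 for non-cortical brain, -0.0283 for pericytes and -0.73 for muscle and skin, the last as a consequence of leaving out the sample with the brightest muscle genes. Among animals numbered over 200 the medians were -0.0242 for WAVE and Arp2/3, -0.0221 for FMRP and translation, 0.0859 for radial glia, 0.12 for intermediate progenitors, 0.16 for interneurons, -0.0568 for ganglionic eminence and striatum, 0.15 for Cajal-Retzius cells and -0.041 for muscle and skin. With the mean of muscle and skin genes as a covariate they were -0.10 for ganglionic eminence and striatum, 0.22 for Cajal-Retzius cells and -0.0467 for muscle and skin.

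With each sample left out in turn, the log2 fold change ranged from -0.35 to 0.12 for Nipa1, from -0.11 to 0.0255 for Ube3a and from -0.0448 to 0.22 for Nipa2. The medians ranged from -0.13 to 0.0169 for ganglionic eminence and striatum, from -0.38 to 0.39 for Cajal-Retzius cells, from -0.56 to 1.29 for muscle and skin, from -0.15 to 0.00968 for axon guidance, from -0.15 to 0.17 for projection neurons, from -0.0292 to 0.19 for pericytes, from -0.21 to 0.0485 for radial glia and from -0.13 to 0.15 for intermediate progenitors.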

Other observations

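The tests on non-neural tissue in transgenic sample 1, on tissue from outside the cortex in wild-type sample 2, on muscle and skin genes in transgenic sample 1 and on cell cycle genes without that sample were chosen only after the results were seen.

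Single embryos differed widely in genes of neighbouring tissues. Ttr, the transthyretin of choroid plexus, stood at a log2 intensity of 13.57, 14.57 and 13.48 in transgenic samples 2 and 3 and wild-type sample 3, and at 9.00, 6.93 and 6.99 in transgenic sample 1 and wild-type samples 1 and 2. Otx2, a transcription factor of choroid plexus and midbrain, ranged from 7.41 in wild-type sample 1 to 12.35 in wild-type sample 2. The cardiac and embryonic muscle actin Actc1 stood at 11.83 in transgenic sample 1 and 9.50 in wild-type sample 3, and between 6.00 and 6.36 elsewhere. Transgenic sample 1 and wild-type sample 3, the pair with animal numbers under 100, were separated from the other 4 in the means of 4 of 31 lists. The 4 lists were muscle and skin (1.63 against -0.82), cell cycle (0.67 against -0.34), erythroid genes (0.33 against -0.16) and Cajal-Retzius cells (-0.48 against 0.24). How many lists a random pair would separate was not computed, so the count alone does not show that the ranges differ.

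Of the 10 splits of the 6 samples into 3 against 3, all 10 gave as many probes past the adjusted threshold as the genotype, since the real count and the highest other count were 0. For lists past the threshold 2 of 10 splits gave as many, 11 for genotype and 13 for the highest other. 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, genotype gave 916 probes. The 4 splits that put transgenic sample 1 and wild-type sample 3, the pair numbered under 100, on one side gave 339, 704, 1164 and 1263, so only part of them exceeded genotype. With the number range as a block, genotype gave 887 higher and 1091 lower probes at an unadjusted p under 0.05, 0 past the adjusted threshold and 12 lists. For 6 of the 29 lists the genotype split had the largest difference of list means of all 10 splits, where 2.9 would by chance if lists were independent. The difference and the highest other were 0.69 and 0.54 for interferon, 0.34 and 0.23 for glycolysis and hypoxia, 0.21 and 0.19 for autism-associated genes and 0.75 and 0.71 for microglia and macrophages, and they were nearly equal for ribosomal proteins and for WAVE and Arp2/3. Of the 11 lists that camera called, 5 are among these 6. For the other called lists another split gave a larger difference, as for synaptic genes, 0.40 against 0.36 for genotype.

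The mean of the interferon response list was higher in all 3 transgenic samples than in any wild-type one. Groups did not overlap for 5 of its 10 tested genes. A candidate explanation is a response to the transgene, which the genotype design names and no test here separates from the following. Non-neural head tissue in transgenic sample 1 is argued against, because the list median was 0.957 without that sample. More macrophages and microglia in the transgenic samples remain open, since the genotype difference of 0.69 in the list mean was 0.324 (95% interval -0.19 to 0.84) with the macrophage list mean as a covariate, and the 2 lists share 0 genes. More meningeal tissue remains open as well, with a difference of 0.739 (95% interval -0.17 to 1.64) given the meningeal list mean, an interval too wide to decide. Of the 10 splits only the genotype split, 1 of 10, gave a difference as large, 0.69 against 0.54 for the highest other, and 10 splits are too few for a share under 0.05.

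On the first principal component, with 51.8% of the variance, transgenic sample 1 lay at 57.1 and wild-type sample 2 at the other end at -30.8, with wild-type sample 1 next at -16.2, while wild-type sample 3 lay at the end of the second, with 19.8%, at -28.3, and genotype was not tested as an explanation of these positions. In transgenic sample 1, 93.3% of the 15 tested muscle and skin genes were highest, which is consistent with muscle and skin tissue in that sample. Their median excess over the other samples was 3.92 on the log2 scale, while the highest of 10000 random lists of the same size, matched on mean intensity, reached 0.716, which argues against a noisy array for those genes. A noisier array may still account for part of its wider scatter. Its deviation from the other arrays had an SD, over oxidative phosphorylation and ribosomal genes, of 1.60 times the median of the other 5 arrays. That SD cannot tell noise from a difference in tissue that alters these genes. In wild-type sample 2, 66.7% of 18 genes of non-cortical brain were highest, with a median excess of 1.86 and other samples highest for the rest. The list mixes several brain regions, so a single tissue need not raise all its genes. That sample also had the lowest means of the interneuron and ganglionic eminence lists, -0.61 and -0.57. Dlx1 stood at 6.16 there, against 11.54 to 12.95 elsewhere, and Tbr1 at 6.61, against 8.99 to 11.14. For projection neurons, at -0.37, transgenic sample 3 was as low, at -0.38. Low Dlx1 and Tbr1 go with tissue from outside the cortex, which stays open because they were picked after being seen.

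The cell cycle list was higher in transgenic samples, and its call was lost without transgenic sample 1. Leaving that sample out makes wild-type sample 3 the only animal numbered under 100, so genotype is then mixed with the number range. The lost call therefore cannot tell that sample from the range. Of the 10 splits of the samples 5 gave a difference of the list mean as large as the 0.39 of genotype, with 0.83 for the highest other. The others as large put transgenic sample 1 and wild-type sample 3, the pair numbered under 100, on one side. They thus also carry the difference between the number ranges, 0.67 against -0.34, over which genotype is balanced. In any case 10 splits are too few for a share under 0.05. Among the 4 animals numbered over 200, which leave out transgenic sample 1, the list median was 0.488 and both transgenic list means lay above both wild-type ones. The difference among those 4 cannot come from transgenic sample 1. This subset also leaves out wild-type sample 3, the wild-type sample with the highest list mean. With wild-type sample 3 kept, the median was 0.09 without transgenic sample 1 and -0.10 without it and wild-type sample 2. Both fits mix genotype with the number range. For the difference over all 6 samples, transgenic sample 1 alone and genotype both stay open. The animal number range holds both genotypes in equal numbers, so using it as a block cannot change the median. The unchanged 0.38 therefore does not test the range.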
